A study of Mus musculus with 6 samples.

How the data were processed

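Gene expression was measured on 6 one-colour Agilent arrays, 1 per sample: 3 KC samples and 3 KCS samples (the same with Setdb1flox/flox), all isolated mouse acinar cells. Per the labels' protocols, total RNA was purified on columns, amplified with a whole-transcriptome kit and labelled with Cy3. Each deposited file holds 62976 spots of 1 array, of which 3671 were controls and 59305 carried 56605 different probes. Per the file headers, the scanner images were read with Agilent Feature Extraction 12.0.3.1, and the processed signal is an intensity in scanner units, already corrected for background by that program. The deposited value table of the series holds log2 values for 36136 probes. Set against the scanner values, its 36110 rows of non-control probes matched log2 signals scaled as below, but with outlier spots kept. Each probe was first centred on its median over the 6 arrays (r = 0.999999 or above, across probes). The scale, centring and direction of the value table are thus known. Its column medians were -0.01, 0.05 and 0.10 for KC replicates 1 to 3 and -0.05, -0.03 and -0.04 for KCS replicates 1 to 3.

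The log2 of the processed signal minus the 75th percentile of each array over non-control probes was the value used. Spots of 1 probe were averaged, spots that the extraction program marked as outliers were left out (88 to 140 per array), and no spot was saturated. Probes well above background on at least 3 of the 6 arrays were tested. Probes were named by matching the accession in the files, without its version, to RefSeq records of GRCm38.p6. The files name another build, so no coordinates are given. A symbol was found for 33767 probes, for 23462 genes, and 22838 probes stayed unnamed and were tested by probe. For the 8057 genes with several probes, the probe with the highest mean over all 6 arrays stood for the gene.

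KCS was compared with KC by the moderated two-sided test of limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values in the text are from limma. Standard errors are those of the fit, and SD is the spread of the 3 samples of a group. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists with at least 5 measured genes. Each list was tested again with the correlation estimated from the data and with fry. Of the genes in the lists, 3 were not in the reference. Each list's genes were also adjusted over the list alone. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the mean of the brighter group over the mean, for the dimmer group, of the higher of the lowest signal well above background on each array and the probe's own signal, on the scaled log2 values. List medians were also taken with such genes at their bound. Arrays give no counting depth. Their number limits the precision, and so do signal at background and differences between the samples of a group.

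The lists, the test and the rule for named genes were fixed before the data were examined. Named were Setdb1, the 10 genes with the largest fitted change in each direction among called genes whose groups did not overlap, up to 4 genes with the smallest p-value in each list that passed and in the p53 and both apoptosis lists, and, whatever their result, Trp53, Cdkn1a, Mdm2, Bax, Bbc3, Krt19, Sox9, Ptf1a, Cpa1 and Bhlha15. Some genes that the rule selects are not reported here. Gene-name families and their example genes in the closing section were chosen after their values were seen.

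The arrays came from 2 slides, the first with KC and KCS replicate 1 and the second with replicates 2 and 3 of both groups. The slide and the prefix of the array labels divide the arrays in the same way, so they are the same block. Alternatives were quantile normalization, median centring, the deposited value table, other filters on dim probes, other rules for several probes, marked spots kept, trend and robust eBayes, array weights, the replicate number and the slide as blocks, the second slide alone, each array left out in turn, and other thresholds. Scaling to the spike-in controls, normexp on the median signals with quantile normalization, list counts with single arrays left out, and the share of equal signs on both slides over all rows were added after the data were seen. Intervals of medians are 95% percentile bootstrap intervals from 10000 resamples of genes, which are not independent. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 in R.

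The steps were tested on simulated data for KCS against KC with 27102 genes, of which 50 were changed by each of 4 sizes. At log2 changes of 0.5 and 1 the share recovered was 0%, at 2 it was 42% and at 4 it was 78%, with median estimates of 0.50, 0.97, 2.10 and 3.96. Among unchanged genes 4 were called, and with no change at all 0 were called. A list shifted on purpose was called by each of the list tests. Far fewer genes were changed than the 16345 called in the data, so the adjusted threshold was stricter. The shares recovered therefore do not give the recovery in the data. The simulated noise was independent between genes, so the list result says little about the test with an estimated correlation in the data.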

Results

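The series compared gene expression in acinar cells isolated from the pancreas of mice of 2 genotypes on a C57BL/6 background. In both, Cre recombinase made under the control of Ptf1a, a gene of the pancreatic lineage, switches on an oncogenic allele (here KC, n = 3). In the second genotype both copies of Setdb1, which encodes a histone H3 lysine 9 methyltransferase, also carry loxP sites that Cre can recombine (here KCS, n = 3). The series title places the comparison in the question of whether Setdb1 is needed for pancreatic ductal adenocarcinoma through its effect on apoptosis that depends on p53. Total RNA was amplified and hybridised to 6 one-colour arrays, 1 per sample. The labels do not say whether each sample came from a separate animal. The sex genes show at least 2 animals in each group, so the spread that the p-values measure is in part between animals and may be in part technical. With 3 arrays per group, their number limits the precision of every value.

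The 2 groups differed in how signal was spread over the array. Of 56605 probes, 26550 to 27237 were well above background on the KC arrays and 35366 to 35920 on the KCS arrays. The 100 brightest probes held 34.4% to 37.4% of the summed signal on the KC arrays and 13.4% to 14.6% on the KCS arrays. The 75th percentile of the processed signal, to which each array was scaled, was 61.2 to 68.6 scanner units on KC arrays and 347 to 423 on KCS arrays. The median log2 signal of the spike-in controls was 9.72 to 10.06 on KC and 9.46 to 9.71 on KCS arrays. All changes are therefore relative to the array's 75th percentile. The median log2 fold change over all 27102 rows tested was -0.19 on that scale and 2.68 when arrays were scaled to the spike-in controls instead, an alternative chosen after the data were seen. Spike-in scaling compares amounts of a transcript only if equal amounts of RNA and of controls went into each reaction. Whether they did is not known here, so its values show what hangs on the scaling and not the change per cell.

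**Figure D1:**
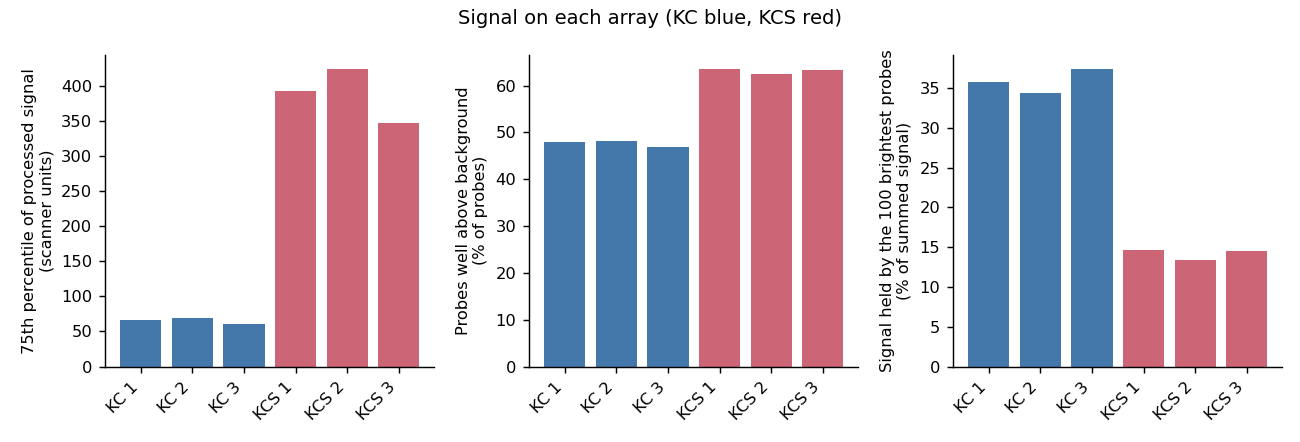
Signal on the 6 arrays, 1 bar per array, KC in blue and KCS in red: the 75th percentile of processed signal in scanner units, the percentage of probes well above background, and the percentage of summed signal held by the 100 brightest probes. The first 2 measures were higher on all KCS arrays (percentile 347 to 423 against 61.2 to 68.6) and the last was lower (13.4% to 14.6% against 34.4% to 37.4%).

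Acinar identity genes were lower in KCS, and markers of fibroblasts and macrophages were higher. Cpa1, a digestive carboxypeptidase, fell by 9.88 ± 2.32 (SE) on the log2 scale, a call that was lost within the second slide alone (adjusted p = 0.0600). The chymotrypsin-like gene Ctrl fell by 13.48 ± 1.37. Timp1, an inhibitor of matrix metalloproteinases, rose by 6.50 ± 0.20 and the macrophage gene Aif1 by 5.38 ± 0.28. Among 27102 rows, 1 per named gene or unnamed probe, 16345 were called with limma at an adjusted p below 0.05: 7016 higher and 9329 lower in KCS. Of the higher calls, 1949 were not well above background on any KC array, and of the lower calls 200 on any KCS array. Their folds are only bounds, and for some called genes the bound was no change. Of the rows with a gene symbol, 5274 were higher and 4738 lower. The 3 arrays of each group did not overlap in 18494 rows (68.2%, where chance gives 10%). The share of calls that were higher was 42.9%, and it was 56.5% with median centring, 96.8% with spike-in scaling and 22.3% without the filter on dim probes. With the slide as a block 17225 rows were called, and over all 27102 rows 88.3% had the same sign on both slides, where independent slides would give 50.4%.

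Setdb1 was represented by 1 probe, which was not lower in KCS. Its scaled log2 signal was -0.91, -1.04 and -0.32 in the KC samples and -0.28, -0.44 and -0.55 in the KCS samples, a log2 fold change of 0.33 ± 0.24 (SE, n = 3 per group, limma adjusted p = 0.270). It was 0.63 within the first slide and 0.18 within the second, and 0.69 with median centring (adjusted p = 0.0443) and 3.21 with spike-in scaling (adjusted p = 1.62e-05). Where the probe lies relative to the part of the gene flanked by loxP sites is not known here, and a probe outside that part checks nothing about the genotype.

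Of 39 lists, 38 had the 5 measured genes the test needed, and 27 were called: 21 higher and 6 lower. With the correlation between genes estimated in each list, none of these calls held. The adjusted p of the called lists was then 0.340 to 0.538, the last for acinar digestive enzymes, and that of the p53 target genes was 0.430. In this test 3 lists had an unadjusted p under 0.05. By contrast fry, which tests whether the genes of a list move one way and does not set it against other genes, called 31, among them Schwann cell and nerve markers (adjusted p = 0.00772), the H3K9 methylation machinery (0.0326) and acute-phase and pancreatitis-associated genes (0.0375). Without the filter on dim probes PanIN and gastric-type mucosa markers (adjusted p = 0.0262, PanIN being pancreatic intraepithelial neoplasia), B and plasma cell markers (0.00941) and the H3K9 methylation machinery (0.00163) passed. Acute-phase and pancreatitis-associated genes passed there too (camera adjusted p = 0.0204), with a median of -1.10. With spike-in scaling 15 lists were called, among them acute-phase and pancreatitis-associated genes (adjusted p = 0.0115). Leaving out single arrays moved the count of risen or fallen genes by over 1.5 times in several lists, which are named with their counts below. In the tuft cell, islet, macrophage, MHC class II, interferon-stimulated, adipocyte, intestinal, immediate-early and cholesterol lists such moves were by 1 gene.

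All 29 measured acinar digestive enzyme genes fell, with a median log2 fold change of -10.62 (camera adjusted p = 3.69e-05, and 0.538 with an estimated correlation). None rose, but the genes that passed were 20 without KC replicate 1, 18 without KC replicate 2, 18 without KC replicate 3 and 17 without KCS replicate 2. With all arrays the count was the same when adjusted over the list alone, as for every list below whose second count is not given. The median was -15.81 within the first slide and -8.06 within the second, and -7.75 with spike-in scaling. By fitted log2 fold change, the 10 named genes that fell most were the pancreatic lipase gene Pnlip (-16.56), the secretory granule gene Zg16 (-14.93), the phospholipase gene Pla2g1b (-13.81), the amylase gene Amy2b (-13.66), Ctrl (-13.48), Serpini2 (-13.46), the kallikrein gene Klk1 (-13.18), the disulfide isomerase gene Pdia2 (-12.63), the elastase gene Cela3b (-12.41) and the carboxypeptidase gene Cpb1 (-12.36). On the KCS arrays, Pnlip, Zg16, Pla2g1b and Serpini2 were well above background on 1 array, and Amy2b, Klk1, Pdia2, Cela3b and Cpb1 on 2. The KCS level of these genes thus rests in part on signal at background, and their order is not known. Amylase, elastase and kallikrein genes belong to families of near-identical copies, so their probes can share signal. The KCS samples differed in what acinar signal they held. The median scaled log2 signal of the enzyme list was -5.32, -1.0 and 7.0 in KCS replicates 1, 2 and 3, against 11.27 to 11.42 in KC. Cpa1 was -1.87, -0.61 and 7.53 against 11.43 to 11.65, and its log2 fold change ran from -12.81 to -8.11 with 1 array left out. Without KCS replicate 3 the median of the list was -14.42, again with 29 genes lower. The calls of Cela3b and Cpb1 ended when any of several single arrays was left out, with adjusted p up to 0.0597 for Cela3b and 0.0688 for Cpb1, both without KCS replicate 2. Within the second slide alone the calls of Klk1 (adjusted p = 0.0532), Pdia2 (0.0528), Cela3b (0.0572) and Cpb1 (0.0793) were lost too.

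Of 11 acinar transcription factor genes, 10 fell and none rose (median -2.87, camera adjusted p = 0.00640). With spike-in scaling the median was 0.01, against 2.68 over all rows, and the list still passed (camera adjusted p = 9.74e-08). The call was lost without the filter on dim probes (adjusted p = 0.142). Bhlha15, which encodes the secretory cell factor MIST1, fell by 9.63 ± 1.62, and Ptf1a, a factor that drives enzyme gene transcription, by 8.80 ± 1.66, with Ptf1a well above background on 1 of 3 KCS arrays. Nr5a2, a nuclear receptor of acinar cells, fell by 3.46 ± 0.44 (adjusted p = 9.08e-04), and by 0.59 with spike-in scaling (adjusted p = 0.154). In the islet endocrine list 13 of 20 genes fell and 2 rose (median -1.64, camera adjusted p = 0.00359). With spike-in scaling its median was 1.24, below the 2.68 over all rows, and it still passed (camera adjusted p = 0.0107). The call of the islet list was lost without the filter on dim probes (adjusted p = 0.189). The glucagon gene Gcg fell by 2.43 ± 0.20 and the prohormone convertase gene Pcsk2 by 2.12 ± 0.16, and these were 0.44 and 0.76 with spike-in scaling.

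Of 25 ductal markers, 11 rose and 5 fell, or 12 and 5 adjusted over the list alone (median 1.15, camera adjusted p = 0.0281). The median was 0.15 within the first slide and 1.21 within the second. The keratin gene Krt7 rose by 5.39 ± 0.29, Anxa3 by 3.84 ± 0.16 and the keratin gene Krt19 by 3.06 ± 0.64 (adjusted p = 0.00669). Krt19 was 4.23, 5.62 and 6.75 in KCS replicates 1, 2 and 3 and 2.0 to 3.07 in KC. Sox9, a progenitor and ductal transcription factor, was -0.49 ± 0.34 (adjusted p = 0.253), and 2.39 with spike-in scaling. The call of the ductal list was lost without KCS replicate 3 (adjusted p = 0.0726), without KC replicate 3 (adjusted p = 0.0554) with every probe on its own (adjusted p = 0.0588) and with spike-in scaling (adjusted p = 0.132). Without KC replicate 2 or KCS replicate 2, 3 of these markers fell. Of 14 markers of pancreatic intraepithelial neoplasia and gastric-type mucosa, 5 rose and 3 fell, or 6 and 3 adjusted over the list alone (median 0.57, or 0.49 with dim genes at their bound, camera adjusted p = 0.350). That median was -1.04 within the first slide, 1.82 within the second and -0.51 without KCS replicate 3, where 5 rose and 6 fell, and it was -1.4 over the PanIN and gastric-type mucosa markers well above background on all arrays. Of 10 tuft cell markers 6 rose and none fell (median 2.3, or 1.64 with dim genes at their bound, camera adjusted p = 0.0132). Dclk1, a kinase used as a tuft cell marker, rose by 3.59 ± 0.39 and was well above background on 2 of 3 KC arrays. The lowest of the 3 probes of Dclk1 was at 2.03. The call of the list was lost with spike-in scaling (adjusted p = 0.165).

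**Figure D2:**
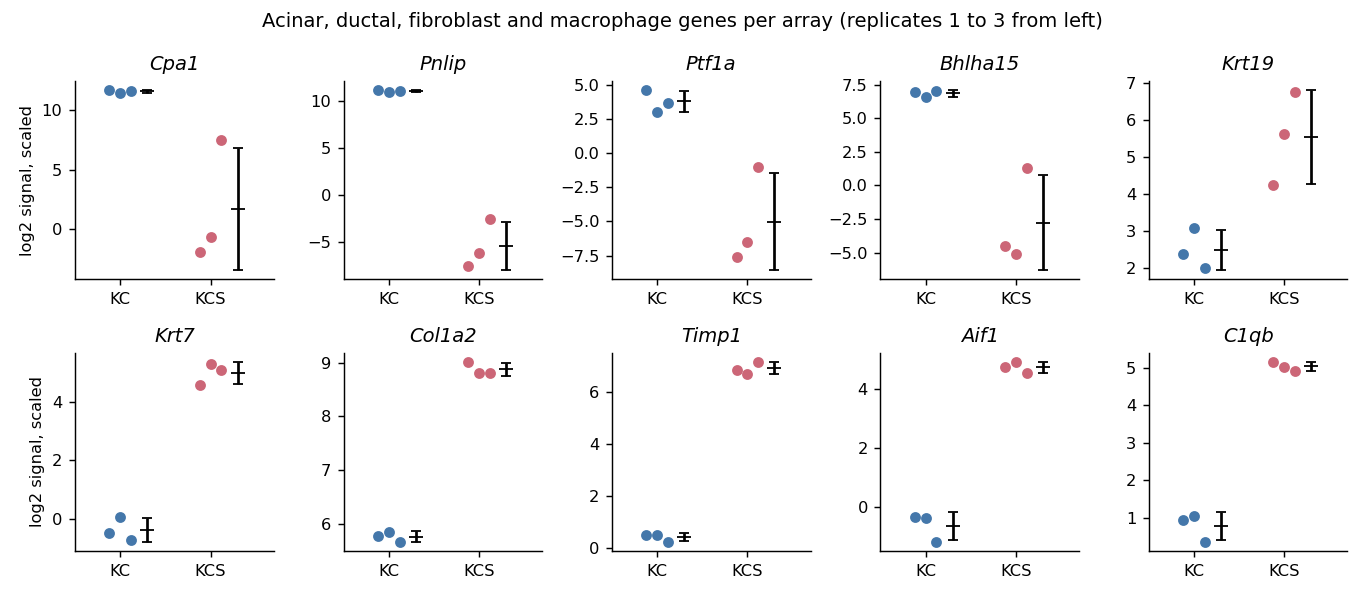
Scaled log2 signal of 10 acinar, ductal, fibroblast and macrophage genes, 1 point per array with replicates 1 to 3 from left to right, KC in blue and KCS in red, and the mean ± SD (n = 3) beside the points. Cpa1 was 11.43 to 11.65 in KC and -1.87, -0.61 and 7.53 in KCS, while Col1a2 and C1qb lay higher on each KCS array than on any KC array.

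The p53 target list gave a mixed picture. Of 40 measured genes, 17 rose, 10 fell and 13 did not pass the test, and the list as a whole did not pass (median 0.15, camera adjusted p = 0.0627). The median was 0.37 within the first slide and 0.12 within the second. The list passed without KC replicate 1 (median 0.14, adjusted p = 0.0330) and without KCS replicate 3 (median 0.20, adjusted p = 0.04995), without the filter on dim probes (adjusted p = 2.44e-05), with the mean of a gene's probes (adjusted p = 0.0482) and with fry (adjusted p = 0.00194). With an estimated correlation its adjusted p was 0.430. Pmaip1, which encodes the BH3-only protein NOXA, was not well above background on any KC array and was at least 60.4-fold higher in KCS (adjusted p = 5.62e-05). Epha2, a receptor tyrosine kinase, rose by 4.26 ± 0.22, Sfn, which encodes a 14-3-3 protein that can arrest the cell cycle, by 3.70 ± 0.24, and Phlda3, an inhibitor of AKT signalling, by 3.21 ± 0.22. Epha2 also stands in the MAPK output list, and Pmaip1 in the list of pro-apoptotic genes. Trp53 itself rose by 1.67 ± 0.22 (adjusted p = 9.96e-04), from -0.74 ± 0.26 to 0.93 ± 0.23 (SD, n = 3), and Bax, an effector of mitochondrial apoptosis, by 1.83 ± 0.22. Mdm2, the ubiquitin ligase of p53, rose by 0.74 ± 0.24 (adjusted p = 0.0341), a call that was lost without any of 4 single arrays (adjusted p up to 0.115, without KCS replicate 2) and with the mean of its probes (adjusted p = 0.231), the second of which was at 0.06. Cdkn1a, the p21 cell cycle inhibitor, was 1.49 ± 0.76 (adjusted p = 0.132), with KC replicate 1 at 3.61 and the other KC arrays at 1.0 and 0.71. Without KC replicate 1 it was 2.41 (adjusted p = 0.00170), it was -0.19 within the first slide and 2.33 within the second, and its second probe was at 2.62. It also passed with the mean of its probes (2.05, adjusted p = 0.00565), array weights (1.82, adjusted p = 0.0423) and the second slide alone (adjusted p = 0.00540). With spike-in scaling Cdkn1a was at 4.37 (adjusted p = 6.82e-04), but that scaling shifts all genes upward and 96.8% of its calls were higher. A pass there is no sign that Cdkn1a itself rose. Bbc3, which encodes PUMA, was 0.24 ± 0.50 (adjusted p = 0.704), with -0.73 within the first slide and 0.72 within the second, and -0.30 without KC replicate 2.

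Of 31 pro-apoptotic genes 19 rose and 3 fell (median 1.20, camera adjusted p = 8.78e-05, and 0.340 with an estimated correlation), with medians of 1.45 and 1.20 within the first and second slide. Bak1, the partner of Bax at the mitochondrial membrane, rose by 3.15 ± 0.20 and the death receptor gene Tnfrsf10b by 2.55 ± 0.23. The anti-apoptotic genes moved the same way. Of 16, 8 rose and 3 fell, or 9 and 3 adjusted over the list alone (median 0.79, camera adjusted p = 0.0352). The call was lost with spike-in scaling (adjusted p = 0.0757). Bcl2a1d, a BCL2 family gene that leukocytes express and that has near-identical copies, rose by 6.58 ± 0.47 and Naip2, an inflammasome sensor of macrophages, by 3.39 ± 0.20. Naip5 fell by 1.62 ± 0.16, but its second probe was at 0.21 and the fold change was 1.25 with spike-in scaling. Beside both apoptosis lists, markers of macrophages rose (median 4.23).

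**Figure D3:**
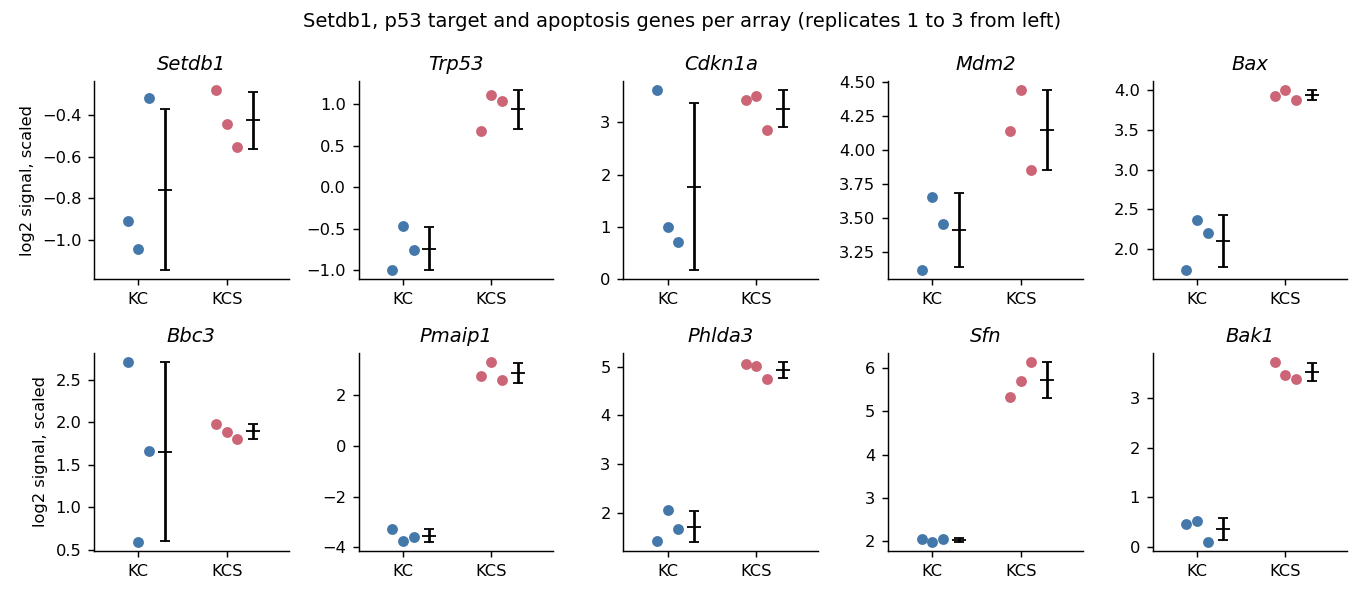
Scaled log2 signal of Setdb1 and of 9 p53 target and apoptosis genes, 1 point per array with replicates 1 to 3 from left to right, KC in blue and KCS in red, and the mean ± SD (n = 3) beside the points. The axes differ between panels; Trp53 was -0.74 ± 0.26 in KC and 0.93 ± 0.23 in KCS, while for Setdb1, Cdkn1a and Bbc3 the groups overlapped.

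Of 31 fibroblast and stellate cell markers 29 rose and none fell (median 3.12, or 3.11 with dim genes at their bound, camera adjusted p = 1.49e-12), with medians of 3.19 and 3.08 within the first and second slide. The collagen gene Col1a2 rose by 3.12 ± 0.17 and the collagen cross-linking enzyme gene Lox by 4.28 ± 0.21. Of 18 endothelial markers 12 rose and none fell, or 13 and none adjusted over the list alone (median 0.94, camera adjusted p = 9.76e-04). Without KCS replicate 1 or KCS replicate 2, 6 rose, and 16 without KCS replicate 3. Ecscr rose by 2.69 ± 0.25 and Eng by 1.93 ± 0.29. The call was lost with spike-in scaling (adjusted p = 0.131). Of 7 mesothelial markers 3 rose and none fell, or 1 and none adjusted over the list alone (median 1.36, camera adjusted p = 0.0255). Without KC replicate 3, KCS replicate 1 or KCS replicate 3, 1 rose. Wt1 rose by 3.50 ± 0.26, and the call of the list was lost without KC replicate 3 (adjusted p = 0.0577), without KCS replicate 3 (adjusted p = 0.0529) and with spike-in scaling (adjusted p = 0.442). Schwann cell and nerve markers (2 rose and 2 fell of 6, median 0.30, adjusted p = 0.512), adipocyte markers (1 rose and 3 fell of 7, or 2 and 4 adjusted over the list alone, median -0.79 and 2.09 with spike-in scaling, adjusted p = 0.804) and erythroid markers (2 rose and none fell of 7, or none adjusted over the list alone, median 0.98, adjusted p = 0.0665) did not pass. Without the filter on dim probes the medians of Schwann cell and nerve markers (-1.03) and adipocyte markers (0.14) had the opposite sign. The erythroid list did pass with the slide as a block (adjusted p = 0.0453), with the replicate block (adjusted p = 0.0377), within the second slide (adjusted p = 0.00480) and without KC replicate 1 (adjusted p = 0.00263), where 6 rose. It also passed with quantile normalization (adjusted p = 0.0307, and 0.0219 with normexp), without the filter on dim probes (adjusted p = 0.0258) and with genes well above background on all arrays (adjusted p = 0.0400). The erythroid median was 0.15 within the first slide and 1.44 within the second. Without KCS replicate 3 1 erythroid marker rose, and 0 without KC replicate 2, KC replicate 3, KCS replicate 1 or KCS replicate 2. Of the intestinal epithelium markers 2 were measured, too few for the list test, and both rose (median 2.3, or 1.72 with dim genes at their bound), while without the filter on dim probes the median of that list was -1.08.

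Of 21 macrophage and monocyte markers 19 rose and none fell (median 4.23, camera adjusted p = 3.72e-10), with medians of 4.44 and 4.12 within the first and second slide. The complement gene C1qb rose by 4.25 ± 0.23. Of 13 neutrophil markers 10 rose and 1 fell (median 3.87, or 2.90 with dim genes at their bound, camera adjusted p = 7.93e-04), with medians of 4.93 and 3.04 within the first and second slide. Among them the alarmin gene S100a9 rose by 5.72 ± 0.42 and the lectin gene Clec4d by 6.18 ± 0.40, the latter well above background on 1 of 3 KC arrays. T and NK cell markers (11 rose and 5 fell of 19, median 1.89, adjusted p = 0.0597) and B and plasma cell markers (4 rose and 1 fell of 11, median 1.57, adjusted p = 0.193) did not pass, and with dim genes at their bound their medians were 0.95 and 0. The T and NK cell list passed without KC replicate 1 (adjusted p = 0.0283) and without KCS replicate 2 (adjusted p = 0.00941), where 12 rose and 3 fell, and with the mean of a gene's probes (adjusted p = 0.0242) and without the filter on dim probes (adjusted p = 8.65e-04). Over the T and NK cell markers well above background on all arrays the median was reversed, at -1.71 (adjusted p = 0.832). Of the B and plasma cell markers 3 fell without KC replicate 1 and 2 without KCS replicate 1. Of 10 MHC class II genes 9 rose and none fell, or 9 and 1 adjusted over the list alone (median 4.24, camera adjusted p = 3.56e-04). Ciita, the activator of their transcription, rose by 4.58 ± 0.60 and H2-Oa was at least 3.68-fold higher, not being well above background on any KC array. Of 15 MHC class I presentation genes 14 rose and 1 fell (median 1.65, camera adjusted p = 4.57e-05). The immunoproteasome gene Psmb8 rose by 3.52 ± 0.30, and Psmb10 was at -2.67 ± 0.20, or 0.21 with spike-in scaling. Of 37 interferon-stimulated genes 35 rose and 1 fell (median 2.15, or 1.95 with dim genes at their bound, camera adjusted p = 1.09e-10). Among them Oas1a rose by 4.14 ± 0.28 and Parp14 by 2.35 ± 0.19. The calls of the neutrophil markers (adjusted p = 0.114) and MHC class II genes (adjusted p = 0.108) were lost with spike-in scaling.

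Genes of secreted inflammatory factors rose beside the markers of macrophages (median 4.23), neutrophils (median 3.87) and fibroblasts (median 3.12), so the cell type that carries the change is not known. Of 17 senescence and secretory-phenotype genes 14 rose and none fell (median 4.81, or 3.97 with dim genes at their bound, camera adjusted p = 1.05e-07). The p15 cell cycle inhibitor gene Cdkn2b rose by 6.98 ± 0.41, with 2 of 3 KC arrays well above background, and the cytokine gene Il6 was at least 19.8-fold higher. Of 23 chemokines 17 rose and none fell (median 4.12, or 3.66 with dim genes at their bound, camera adjusted p = 2.56e-07). Cxcl16 rose by 5.44 ± 0.32. By fitted log2 fold change, the 10 named genes that rose most were the acute-phase gene Saa3 (10.83 ± 0.78), the collagen gene Col10a1 (8.92 ± 1.03) and the cathepsin gene Ctse (7.84 ± 0.79), each well above background on 1 of 3 KC arrays, and 7 genes not well above background on any KC array. These were the ectonucleotidase gene Nt5e (at least 111-fold), the laminin gene Lama1 (at least 146-fold), the activin subunit gene Inhba (at least 80.8-fold), the cytokine gene Il1b (at least 70.1-fold), the arginase gene Arg1 (at least 117-fold), Sirpb1b (at least 107-fold) and Mab21l4 (at least 51.4-fold). The KC level of these 10 genes rests in part on signal at background, so their order and their rank above other genes are not known. The second probe of Inhba was at 4.16 and that of Il1b at 6.11, both below the printed bound. The acute-phase and pancreatitis-associated list as a whole did not pass (7 rose and 4 fell of 14, or 7 and 6 adjusted over the list alone, adjusted p = 0.223), and its median of 0.42 and its test pointed up while its mean was -1.0 and its median with dim genes at their bound was -0.27. In this list 2 fell with any single KC array left out, 1 without KCS replicate 2 and 7 without KCS replicate 3. The median of the acute-phase and pancreatitis-associated genes was -1.10 without the filter on dim probes, where the list passed (camera adjusted p = 0.0204). It was -4.66 with probes well above background on all arrays, where the list did not pass (camera adjusted p = 0.987).

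Of 37 proliferation genes 25 rose and none fell (median 0.97, or 0.91 with dim genes at their bound, camera adjusted p = 4.70e-07), with medians of 0.53 and 1.28 within the first and second slide. The count that rose was 17 without KC replicate 2 or KCS replicate 3 and 27 without KC replicate 1, moves within 1.5 times. The replication licensing genes Mcm3 and Mcm4 rose by 3.66 ± 0.20 and 2.91 ± 0.21, and the lowest of the 3 probes of Mcm3 was at 2.69. Of 23 MAPK output genes 17 rose and 1 fell (median 2.54, or 1.5 with dim genes at their bound, camera adjusted p = 4.14e-07). The transcription factor gene Etv4 was at least 13.8-fold higher, not being well above background on any KC array. Of 24 immediate-early and dissociation stress genes 13 rose and 2 fell (median 1.30, camera adjusted p = 4.38e-04), with medians of 1.91 and 0.97 within the first and second slide. Egr2 rose by 5.22 ± 0.29 and Socs3, a feedback inhibitor of cytokine signalling, by 3.60 ± 0.21. The call was lost with spike-in scaling (adjusted p = 0.131).

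Genes of protein synthesis and respiration were lower relative to the array's 75th percentile. All 41 cytosolic ribosomal protein genes fell (median -1.43, camera adjusted p = 1.09e-10), but the call was lost with quantile normalization (median 0.05, adjusted p = 0.639), with normexp (adjusted p = 0.956) and with spike-in scaling (median 1.44, adjusted p = 0.447). Rpl32 was at -2.25 ± 0.19 and Rpl35 at -2.02 ± 0.18, and these were 0.62 and 0.86 with spike-in scaling. With quantile normalization Rpl35 was at 0.14 and Rpl32 at -0.43 (adjusted p = 0.0600), so neither call held. Of 35 oxidative phosphorylation genes 24 fell and none rose, or 25 and none adjusted over the list alone (median -0.84, camera adjusted p = 1.10e-04), a call that was lost with spike-in scaling (median 2.04, adjusted p = 0.473). Uqcrq, a complex III subunit gene, was at -1.90 ± 0.18 and Sdhb, a complex II subunit gene, at -1.50 ± 0.17, and these were 0.98 and 1.38 with spike-in scaling. The second probe of Sdhb was at -0.89. Of 25 unfolded protein response genes 17 fell and 2 rose, or 17 and 3 adjusted over the list alone (median -1.28, camera adjusted p = 0.0156). With spike-in scaling the median was 1.60, below the 2.68 over all rows, and the list still passed (camera adjusted p = 0.00569). The call was lost without the filter on dim probes (adjusted p = 0.549) and with genes well above background on all arrays (adjusted p = 0.0502). Ero1b, an oxidase of secretory cells, fell by 6.17 ± 0.37 and Herpud1, a factor of protein degradation in the endoplasmic reticulum, by 3.91 ± 0.21. Of 16 NRF2 target genes 9 rose and 3 fell, or 10 and 3 adjusted over the list alone (median 1.67, camera adjusted p = 0.0162). Cbr3 rose by 2.81 ± 0.20 and Abcc4 by 2.34 ± 0.21. Of 20 glycolysis and hypoxia genes 12 rose and 4 fell (median 0.90, or 0.78 with dim genes at their bound, camera adjusted p = 0.0224). The phosphofructokinase gene Pfkp rose by 2.45 ± 0.29 and Egln3 was at least 1.62-fold higher. Of 21 cholesterol synthesis genes 14 rose and 1 fell, or 14 and 2 adjusted over the list alone (median 0.74, camera adjusted p = 0.00280). Hsd17b7 rose by 3.25 ± 0.37 and Cyp51 by 2.08 ± 0.21. The calls of the NRF2 target genes (adjusted p = 0.612) and glycolysis and hypoxia genes (adjusted p = 0.25) were lost with spike-in scaling.

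Of 14 measured clustered protocadherin beta genes 13 rose and 1 fell (median 3.05, or 1.41 with dim genes at their bound, camera adjusted p = 2.15e-05, and 0.340 with an estimated correlation), with medians of 3.26 and 2.76 within the first and second slide. In 12 of them the gene was not well above background on any array of 1 group. Such a gene passed the filter only through the arrays of the other group, so the filter favoured a difference in it. The camera test used its signal at background. The count of risen genes and the test are thus not independent of the filter. Pcdhb21 rose by 3.18 ± 0.17, with 2 of 3 KC arrays well above background, and Pcdhb16 was at least 3.82-fold higher. These genes have near-identical copies, so their probes can share signal. The call was lost with spike-in scaling (adjusted p = 0.108). Markers of fibroblasts (median 3.12) and macrophages (median 4.23) rose in the same samples, so a tie of this rise to Setdb1 within acinar cells is not shown. The germline genes (3 rose and 3 fell of 9, adjusted p = 0.918) did not pass, and their median of -0.28 had the opposite sign to their mean of 0.25, to their test and to their medians of 2.60 with spike-in scaling, 0.17 with quantile normalization and 0.07 with median centring. The imprinted genes (7 rose and 3 fell of 19, median 0.04, or 0 with dim genes at their bound, adjusted p = 0.463) and the H3K9 methylation machinery (6 rose and 2 fell of 20, median 0.17, adjusted p = 0.192) did not pass either. Of the imprinted genes 4 rose without KC replicate 2 or KCS replicate 3, and 3 without KC replicate 3 or KCS replicate 2. Of the H3K9 methylation machinery 4 fell without KC replicate 2, and 1 without KCS replicate 2 or KCS replicate 3. The median of the imprinted genes was -0.36 within the first slide and 0.35 within the second, -0.27 without the filter on dim probes and -0.15 to 0.17 with 1 array left out.

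**Figure D4:**
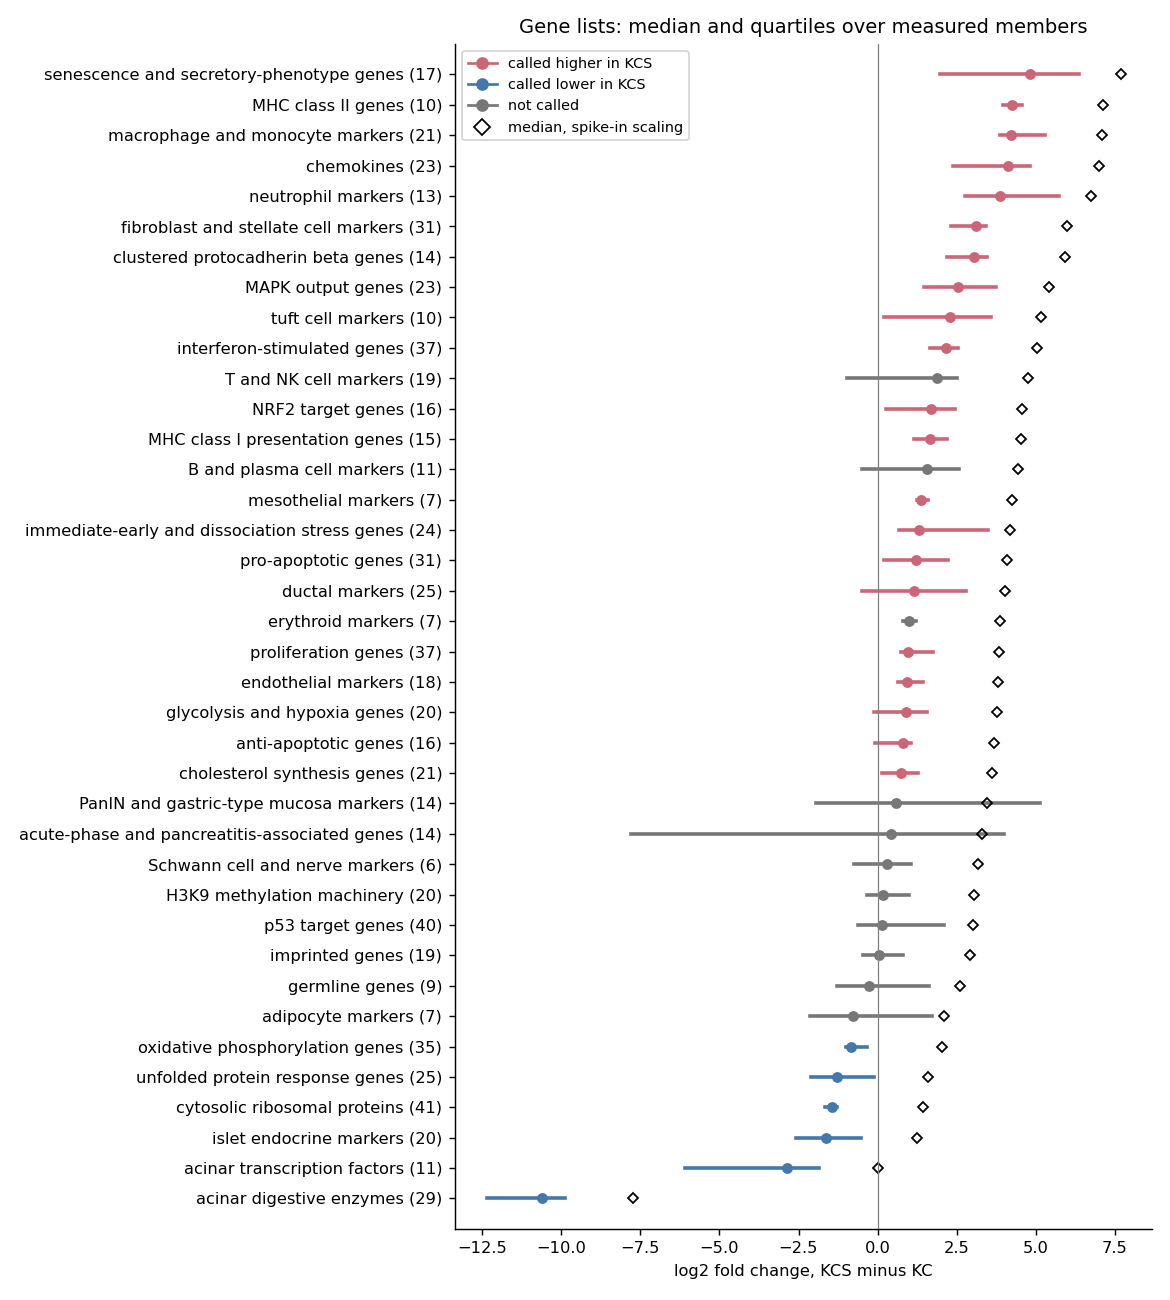
Log2 fold change (KCS minus KC) of the 38 tested gene lists, with the number of measured genes in brackets: points are medians and bars span the quartiles over the genes of a list, red for lists called higher, blue for lower and grey for those not called, and open diamonds are medians with spike-in scaling. The medians run from -10.62 for acinar digestive enzymes to 4.81 for senescence and secretory-phenotype genes; with spike-in scaling 5 of the 6 lists called lower have medians above 0, and the acinar digestive enzymes stay at -7.75.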

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

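The spike-in scaling, normexp on median signals, the list counts with single arrays left out and the share of equal signs on both slides were chosen after the data were seen; the other alternatives were planned. Apart from Setdb1, the p53 target genes and the pro-apoptotic genes, whose changes are given singly below, 732 values of gene lists and 1879 of named genes kept their direction and side of the threshold, 47 and 24 lost the call, 19 and 6 gained it, and 25 and 13 reversed, some of which lost the call too. The list test did not take up trend and robust eBayes or array weights. The list p-values under these settings, for 36 lists each, are those of the main test and could not change. The deposited value table and marked spots kept nearly repeat the main data, so the counts that stayed the same overstate how far the results were put to the test. The planned normexp on mean signals was not run, since the files hold no column of them.

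Under spike-in scaling, which shifts all genes of an array alike, 23624 genes were called higher and 788 lower, 15 lists were called, and Setdb1 was at 3.21 (adjusted p = 1.62e-05). It reversed Sox9 (2.39), Psmb10 (0.21), Naip5 (1.25), Gcg (0.44), Pcsk2 (0.76), Uqcrq (0.98), Sdhb (1.38), Rpl32 (0.62), Rpl35 (0.86) and Ssr4 (0.076), and the medians of acinar transcription factors (0.010), islet endocrine markers (1.24), adipocyte markers (2.09), unfolded protein response genes (1.6), germline genes (2.6), oxidative phosphorylation genes (2.04) and cytosolic ribosomal proteins (1.44). Of these lists, acinar transcription factors (camera adjusted p = 9.74e-08), islet endocrine markers (0.0107) and unfolded protein response genes (0.00569) still passed under spike-in scaling. The medians of these lists lay below the 2.68 over all rows, and camera sets a list against the other genes. Quantile normalization reversed Rpl35 (0.14), germline genes (0.17) and cytosolic ribosomal proteins (0.047). Normexp together with quantile normalization reversed Rpl35 (0.022) and germline genes (0.11), which quantile normalization alone reversed too. Median centring reversed germline genes (0.075) and called Setdb1 (0.69, adjusted p = 0.0443). Over the alternatives with a test, leaving out arrays aside, the smallest adjusted p of Setdb1 was that of spike-in scaling.

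Without the filter on dim probes 31885 genes were called, 24768 of them lower, and the p53 target genes passed (median 0.15, adjusted p = 2.44e-05). The lowest scaled signal well above background was -3.09 to -2.92 on KC arrays and -5.41 to -5.23 on KCS arrays, so a probe at the background of every array falls on this scale. The missing filter reversed intestinal epithelium markers (-1.08), adipocyte markers (0.14), Schwann cell and nerve markers (-1.03), imprinted genes (-0.27) and acute-phase and pancreatitis-associated genes (-1.10), and ended the calls of acinar transcription factors (adjusted p = 0.142), islet endocrine markers (0.189) and unfolded protein response genes (0.549). Probes well above background on all arrays, a smaller set of genes, reversed PanIN and gastric-type mucosa markers (-1.4), T and NK cell markers (-1.71) and acute-phase and pancreatitis-associated genes (-4.66). Every probe on its own reversed germline genes (0.45) and imprinted genes (-0.13). Apart from the filters and scalings, the cause was not tested.

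The p53 target genes also passed with the mean of a gene's probes (median 0.17, adjusted p = 0.0482) and with fry (median 0.15, adjusted p = 0.00194). With an estimated correlation camera called 0 lists, and the pro-apoptotic genes (median 1.20) had an adjusted p of 0.340; 3 lists had an unadjusted p under 0.05, and fry called 31.

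With single arrays left out, 13399 to 15283 genes and 25 to 30 lists were called. The p53 target genes passed without KC replicate 1 (camera adjusted p = 0.0330) and without KCS replicate 3 (0.04995). The medians ranged from 0.056 to 0.25 for p53 target genes, 1.10 to 1.24 for pro-apoptotic genes, -0.51 to 1.63 for PanIN and gastric-type mucosa markers and -0.15 to 0.17 for imprinted genes, and the log2 fold changes from 0.19 to 0.55 for Setdb1 and -0.30 to 0.76 for Bbc3. Within the second slide, with 2 arrays per group, 14038 genes were called, and the calls of Cpa1 (adjusted p = 0.0600), Klk1 (0.0532), Pdia2 (0.0528), Cela3b (0.0572), Cpb1 (0.0793) and Mdm2 (0.153) ended.

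With the replicate block 16452 genes were called, 6871 of them higher, and 28 lists. The deviations of samples with the same number from their group means correlated at 0.33, 0.04 and 0.14 across genes, and KCS replicate 2 correlated best with KC replicate 3 (0.18), so the numbers were not taken to pair the samples. With the slide as a block 17225 genes and 28 lists were called. Under both blocks the erythroid markers passed (adjusted p = 0.0377 and 0.0453).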

Other observations

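The tests on the acinar, fibroblast and macrophage genes and on the ribosomal and oxidative phosphorylation genes were chosen after the results were seen. The splits of the samples and the olfactory receptor tests were written before their deciding values were seen, but the olfactory receptors themselves were picked after their counts and largest changes were seen. How the spike-in tests on the ribosomal and olfactory genes, the test on KCS replicate 3 and the count of fibroblast and macrophage markers are read was also settled after their values were seen.

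The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 16345 genes and the highest of the others 0, so 1 of 10 splits gave as many. It called 27 lists and the highest of the others 22, again 1 of 10. The other splits called 12 to 22 lists, so camera at the preset correlation calls many lists in splits that mix the genotypes as well. Each of these splits sets unequal numbers of the genotypes against each other. Part of the genotype difference thus stays in the comparison, and the rest widens the spread. Neither the 12 to 22 lists nor the 0 genes show what would be called without a difference.

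Acinar genes fell while fibroblast and macrophage markers rose. The 75th percentile scaling is not the whole cause of the fall, since the median of the acinar digestive enzymes stayed at -7.75 with spike-in scaling. Even dilution of acinar cells would raise the other cell types alike, but the fibroblast median exceeded the islet median by 4.76 (bootstrap interval 3.68 to 5.66). Both medians were known when this pair was chosen, and a separate change of the islet genes was not tested. The gap thus speaks at most against even dilution as the whole cause. More fibroblasts and macrophages in the KCS preparations stay open as an explanation: 92.3% of their measured markers rose and none fell, but these markers are the pattern itself, so this count does not support it. A change of gene expression within acinar cells was not tested and stays open, and for the p53 target, apoptosis, secretory, chemokine, protocadherin and other lists that rose the cell type that carries the change is open too.

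Ribosomal protein and oxidative phosphorylation genes fell relative to the 75th percentile. With spike-in scaling the median over the genes of both lists was 1.74. That scaling moves the median of all genes and probes tested from -0.19 to 2.68, so the shift alone set the sign, and the genes still lay below the median of all genes and probes tested. With quantile normalization the ribosomal median was 0.05, against -0.01 over all genes and probes tested. The oxidative phosphorylation median was -0.37 with quantile normalization, where its call held, and -0.48 with median centring. These values do not decide whether the scaling accounts for the fall, and no biological explanation was tested.

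Of 134 measured olfactory receptors 90 fell and 15 rose, with a median of -1.92, and of -1.49 with quantile normalization and -1.57 with median centring. With dim genes at their bound the median was also -1.92. The filter also passed receptors well above background on the KC arrays alone. Background lies lower on the scaled KCS arrays, so the filter favoured a fall in these. Among the smallest p-values, Olfr1062, Olfr116, Olfr370, Olfr522 and Olfr1428 were of this kind, but Olfr1347 was not. With spike-in scaling the median was 0.96 (bootstrap interval 0.63 to 1.49), below the median of 2.68 over all genes and probes tested, and 40 receptors stayed lower. The shift of that scaling alone set the sign, so the test does not decide whether the scaling accounts for the fall. Cross-hybridisation with acinar transcripts would raise the receptors on KCS replicate 3, which held the most acinar signal of the KCS arrays, but that array differed from the mean of the other KCS arrays by -0.55 (interval -0.64 to -0.49), against -0.43 over all genes and probes tested. A single array excludes nothing, so scaling and cross-hybridisation both stay open as explanations. How far the filter set the fall was not tested, and no biological explanation was tested.

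Of the called probes without a gene symbol 4591 fell and 1742 rose (72.5% fell), and of the called named genes 47.3% fell. The difference was not tested, and unnamed probes stand singly while the brightest probe stands for a named gene. The medians were -0.60 and 0.07, and 2.28 and 2.95 with spike-in scaling.

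Of 35 gene-name families looked at, 24 had more genes higher than lower. Matrix metalloproteinases rose in 12 of 16 and fell in 1 (median 3.69), with Mmp7 at 5.71 and Mmp14 at 4.63. Collagen chains rose in 26 of 37 and fell in 6 (median 1.98, or 1.84 with dim genes at their bound), with Col8a1 at 6.75. Integrin subunits rose in 18 of 23 and fell in 1 (median 2.37, or 2.19 at the bound), with Itgav at 2.99. Laminin chains rose in 9 of 11 and fell in 1 (median 1.56). Cathepsins rose in 11 of 13 and none fell (median 2.36), with Ctss at 5.31. Wnt ligands rose in 11 of 12 and fell in 1 (median 2.43, or 2.20 at the bound), with Wnt2 at 5.80, well above background on 2 of 3 KC arrays. Toll-like receptors rose in 7 of 12 and fell in 1 (median 2.70, or 1.77 at the bound), with Tlr2 at 3.74. These medians were also above 0 with quantile normalization. Spike-in scaling raises the fold change of every gene alike, so it could not have turned them and tests nothing here. All 12 Klk1b kallikreins fell (median -10.00, and -7.12 with spike-in scaling), with Klk1b21 at -9.44, and their near-identical copies can share signal. Of 16 translocon and signal peptidase genes of the endoplasmic reticulum 12 fell and 2 rose (median -1.25, and 1.63 with spike-in scaling), with Ssr4 at -2.80 (0.08 with spike-in scaling) and Sec11c at -2.93 (adjusted p = 0.864 with spike-in scaling).

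The sex genes differed between samples within both groups. Xist was at -0.72, -0.57 and -5.07 in KC replicates 1 to 3 and at -0.98, -7.58 and -7.42 in KCS replicates 1 to 3, and the Y-linked gene Eif2s3y was at -5.16, -5.12 and 1.40 and at -7.47, 1.64 and 1.28. Both groups thus held mice of both sexes, but not in equal shares: KC replicate 3 and KCS replicates 2 and 3 showed the male pattern. Sex was not in the model. None of the 5 sex genes was called, but with both sexes in each group their spread was wide. The lack of a call thus does not show that the sexes were balanced.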
